A study of Mus musculus with 21 samples.

How the data were processed

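Small RNA libraries made with the QuantM-tRNA-seq method from Trizol-extracted total RNA were available for 21 samples. Per the submitters' processing notes, cutadapt, Bowtie2, featureCounts and DESeq2 were used with the mm10 build; versions and settings are not given in the sources used here. The authors deposited a table of raw read counts per tRNA for each tissue, whole numbers that were not normalized, and all columns were matched to samples by name. The authors also deposited tables of log2 fold changes, p-values and adjusted p-values, per tRNA and per anticodon, and a test statistic, a score with no fixed range. A mean signal per tRNA, counts divided by size factors and averaged over a tissue's libraries, also stands in the authors' deposited tables, per the file headers. In the authors' anticodon table for cerebrum, the mean level of Ser-TGA differed by 35.0% from the summed counts, and all other rows by at most 0.365%; the reason was not found. How reads that fit several near-identical isodecoders were assigned is not given in the sources used here.

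One row of each count table is a bacterial glutamine tRNA spike-in. It was kept out of library sizes and tests and held 0.222% to 0.374% of counts in cerebrum and 0.401% to 1.08% in cerebellum. Nuclear positions of isodecoders were not used here. The 22 mitochondrial rows were matched to genes of the GENCODE M21 annotation (mm10) by amino acid, and the anticodon was found in the middle of all 22 gene sequences.

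Tests across tRNAs used edgeR 4.0.16 with limma 3.58.1 in R 4.3.3: TMM scaling, filterByExpr by group with its minimum count of 10, robust quasi-likelihood fits, two-sided F tests and Benjamini-Hochberg adjustment with a threshold of 0.05. The standard error of a log2 fold change was taken as its size over the square root of F. Each tissue was fitted alone, while the difference between tissues and the wildtype tissue comparison used all 21 libraries and the 204 tRNAs in both tables. Anticodon counts were summed over isodecoders, nuclear and mitochondrial apart. CPM values are counts scaled to a common library size with TMM, computed here from the deposited counts. Mitochondrial shares and spike-in ratios were compared with exact two-sided permutation tests, p being the smaller tail doubled, and the Wilson method gave the 95% intervals, which cover counting error only.

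Lists were fixed before the data were examined: each nuclear isotype, initiator methionine, selenocysteine, families with introns, anticodons starting with adenosine read as inosine, tRNAs with a long variable arm, Arg-TCT, Ile-TAT, mitochondrial tRNAs, and the lowest and highest abundance terciles of nuclear tRNAs. Those with at least 3 measured members were tested with camera at a preset correlation of 0.01; 28 were tested per tissue, and selenocysteine, suppressor (Sup) and Ile-TAT had too few members. No list of cell type markers can be made for a tRNA library. Named tRNAs followed a rule fixed at the same time. For each tRNA comparison between genotypes, all that passed were named if 24 or fewer, otherwise the 12 highest and 12 lowest of those passing. Where fewer than 10 passed, the lowest p-values were added up to 10. Up to 3 features each of iMet, SeC, Arg-TCT and Ile-TAT were always named. For anticodons all passing were named if 12 or fewer, otherwise 6 from each side, with at least 4 by lowest p. For the difference between tissues and the tissue comparison, the 6 highest and 6 lowest of those passing were named. Tyr-GTA-1, Arg-CCG-2-1 and list members outside this rule were named after their values were seen.

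The steps were tested on 20 simulated sets drawn from the real means, library sizes and dispersions. With 20 tRNAs changed by 1.5-fold and 20 by 2-fold, 75.9% and 95.2% were recovered in the cerebrum comparison (206 tRNAs in the first set) and 72.1% and 95.6% in cerebellum (200 tRNAs). False calls made up 4.49% and 4.72% of calls. Each tRNA was drawn independently of the others, so these shares do not cover errors from tRNAs that vary together across libraries. In sets where all nuclear tRNAs fell by 1.3-fold, a log2 change of −0.38, the cerebrum comparison gave a median nuclear change of −0.04 with TMM scaling and −0.37 with mitochondrial total scaling, and the mean over sets of the median mitochondrial change was 0.33 with TMM.

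Alternatives fixed before the data were examined were RLE size factors, library totals, mitochondrial total scaling, DESeq2 1.42.0, limma-voom, no filter, a mean count of at least 50, sex as a covariate, a joint fit, nuclear tRNAs only, leaving out each library, and a block on the replicate number. Chosen after the data were examined were scaling by the median of ratios over mitochondrial tRNAs, spike-in scaling, depth class as a covariate (with mitochondrial scaling also without cerebellum mutant 1 or wildtype 5), and leaving out cerebellum mutants 1 and 5. No pair of replicates agreed within sampling noise: the lowest chi-square per degree of freedom between libraries of a group was 46.2.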

Results

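Transfer RNA was profiled in the cerebrum and cerebellum of C57BL/6J mice that carried a Polr3a mutation switched on by tamoxifen, and of wildtype mice that received the same drug. Polr3a encodes the largest subunit of RNA polymerase III, the enzyme that makes nuclear tRNAs. The series is described as a mouse model of Polr3-related disease, so the question was how the mutation altered tRNA levels in both brain regions. Recombination was induced at postnatal day 28 and tissue was frozen at day 42. QuantM-tRNA-seq, a tRNA library method, gave 21 libraries: 4 mutant and 6 wildtype from cerebrum, 5 mutant and 6 wildtype from cerebellum. The labels give each library a sex but do not say that libraries came from separate animals, so p-values measure only the spread between these libraries. Polr3a itself is not measured by a tRNA library, so the mutation could not be checked in these counts.

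The cerebrum libraries held 4365247 to 7614658 counts. The cerebellum libraries held 1628057 to 7158467 counts and fell into separate depth classes. The shallow class, 1628057 to 2286338 counts, held mutant 1 and wildtype 1, 2, 3, 4 and 6. The deep class, 4884664 to 7158467 counts, held mutants 2, 3, 4 and 5 and wildtype 5. Depth class and genotype were therefore nearly the same split of the cerebellum libraries. The tables listed 209 tRNAs in cerebrum and 208 in cerebellum, 22 of them mitochondrial in each. Each isodecoder, a tRNA sequence sharing its anticodon with sister sequences, was counted alone, and counts of near-identical isodecoders are uncertain because reads can be split between them.

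Mitochondrial tRNAs are not made by RNA polymerase III, and their share of the tRNA counts was higher in mutants of both tissues. In cerebrum the share was 14.3% ± 1.19 (SD, n = 4) in mutants and 11.2% ± 0.445 (SD, n = 6) in wildtype, and all 4 mutants lay above all 6 wildtype libraries (exact two-sided permutation p = 0.00952, the smallest that 210 splits allow; adjusted p = 0.0286 over 6 library measures). In cerebellum it was 17.2% ± 3.005 (SD, n = 5) in mutants and 13.4% ± 0.7002 (SD, n = 6) in wildtype, with 4 mutants above every wildtype library (exact permutation p = 0.00866, adjusted p = 0.026). Each table also has a row named as a bacterial glutamine tRNA spike-in; the amount and the step at which it was added are not given in the sources used here, so ratios to it assume an equal amount per library. The log2 difference of nuclear tRNA counts per spike-in count, mutant minus wildtype, was −0.36 ± 0.12 (SE; exact permutation p = 0.0286, adjusted p = 0.0572) in cerebrum and −0.57 ± 0.21 (SE; exact permutation p = 0.026, adjusted p = 0.052) in cerebellum, and neither passed after adjustment. Mitochondrial counts per spike-in count differed by 0.04 ± 0.13 (SE; exact permutation p = 0.743) in cerebrum and −0.17 ± 0.24 (SE; exact permutation p = 0.498) in cerebellum.

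Within the shallow cerebellum class the single mutant had a mitochondrial share of 21.2% (95% Wilson interval 21.1 to 21.2, counting error only), against a mean of 13.3% in 5 wildtype libraries. Within the deep class, 4 mutants had a mean of 16.1% and the single wildtype library 13.8%. The mean within-class difference was 5.10 percentage points (exact permutation within classes, p = 0.0667, the smallest that these classes allow, so this test could not reach 0.05).

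**Figure D1:**
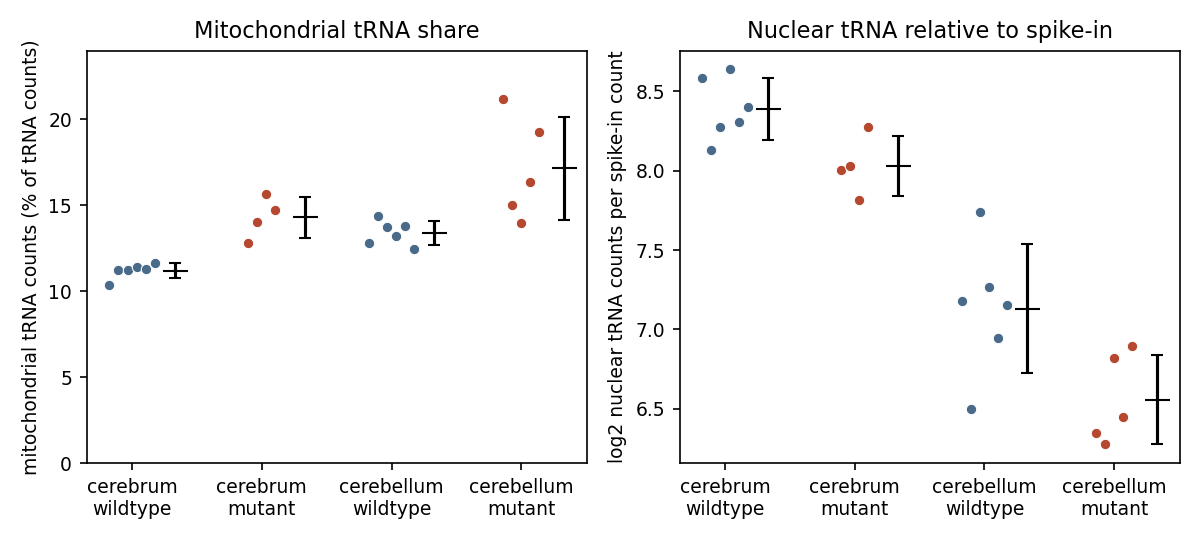
Mitochondrial tRNA counts as a percentage of tRNA counts (left) and log2 nuclear tRNA counts per spike-in count (right) in each library, with the group mean and SD beside the points. The cerebrum mutants lie between 12.8% and 15.7%, above the wildtype range of 10.4% to 11.7%.

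The cerebrum comparison asked which tRNAs differed in mutants relative to the rest of the pool. Of 208 tRNAs tested, 41 passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 17 higher and 24 lower. All 24 lower ones were nuclear isodecoders, and 15 of the 17 higher ones were mitochondrial. The steepest fall was in Met-CAT-4-1, an elongator methionine tRNA, from 195 ± 52.9 CPM (SD, n = 6) in wildtype to 57.9 ± 12.8 CPM (SD, n = 4) in mutants (log2 fold change −1.75 ± 0.21 SE, edgeR adjusted p = 4.72e-06). Ala-AGC-1-1, an alanine tRNA, fell from 134 ± 16.0 to 43.8 ± 5.76 CPM (−1.62 ± 0.16 SE, edgeR adjusted p = 3.37e-07). More abundant isodecoders fell too: Lys-TTT-2 from 2994 ± 362 to 1621 ± 383 CPM (−0.88 ± 0.15 SE) and Tyr-GTA-1, named after its value was seen, from 17980 ± 2871 to 11600 ± 2540 CPM (−0.63 ± 0.15 SE).

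Other named falls on the log2 scale were −1.25 for Trp-CCA-6-1, −1.13 for Leu-CAA-4-1, −1.11 for Ala-AGC-5, −1.03 for Ser-GCT-1-1, −1.02 for Val-CAC-1-1, −0.96 for Thr-AGT-6-1, −0.91 for Val-AAC-2, −0.78 for Arg-TCT-5-1 and −0.78 for Met-CAT-6-1. Among mitochondrial tRNAs the highest were Val-TAC (mt-Tv, mm10 chromosome M, 1025 to 1093, plus strand) at 0.59 ± 0.11 (SE), Gln-TTG (mt-Tq, 3772 to 3842, minus strand) at 0.56 ± 0.17 and Ser2-GCT (mt-Ts2, 11613 to 11671, plus strand) at 0.51 ± 0.10. Leu2-TAG (0.50), Trp-TCA (0.48), Arg-TCG (0.48), Lys-TTT (0.47), Cys-GCA (0.45), Met-CAT (0.44), Glu-TTC (0.44) and Asp-GTC (0.43) of the mitochondria also rose. Among these, Gln-TTG did not pass without cerebrum mutant 1, Cys-GCA without mutant 2, 3 or 4, Glu-TTC without mutant 3 or 4 or wildtype 3, and Trp-TCA without wildtype 2. Cys-GCA-3 did not pass without mutant 3 or wildtype 3, nor Met-CAT-6-1 without mutant 1 or 3 or wildtype 3, 4 or 5. Trp-CCA-6-1 and Met-CAT-6-1 rested on mean counts of only 38.2 and 94.1 per library. The only nuclear tRNAs to rise were Cys-GCA-3 at 0.51 and Arg-CCG-2-1 at 0.40, the latter named after its value was seen. Initiator methionine tRNAs iMet-CAT-1, iMet-CAT-3-1 and iMet-CAT-2-1 (0.17, 0.19 and 0.16) and selenocysteine SeC-TCA-1-1 (0.16) did not pass, and lay below 0 when scaled to the mitochondrial total (−0.22, −0.20, −0.23 and −0.23) or to the spike-in. The isoleucine tRNAs Ile-TAT-2 and Ile-TAT-1-1 (−0.07 and −0.05) did not pass either, though both did on the mitochondrial scale (−0.46 and −0.44). Arg-TCT-4-1, known as a neuron-enriched arginine tRNA, did not pass at 0.37 ± 0.14 (SE, edgeR adjusted p = 0.0641), nor did Arg-TCT-1-1 at 0.24 and Arg-TCT-3-1 at −0.08; on the mitochondrial scale these were at −0.02, −0.15 and −0.47, and the last passed.

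These directions depend on what is held constant. The median of all cerebrum tRNAs moved from −0.03 with TMM to −0.41 with libraries scaled to their mitochondrial total. The median nuclear tRNA was at −0.07 with TMM scaling and at −0.46 with mitochondrial scaling, and the median mitochondrial tRNA moved from 0.42 to 0.03. Scaled that way, 111 cerebrum tRNAs passed, 0 higher and 111 lower, and the 24 nuclear falls were among them, while the rises of mitochondrial tRNAs and of Cys-GCA-3 no longer passed. With library totals alone the split was 6 higher and 25 lower.

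**Figure D2:**
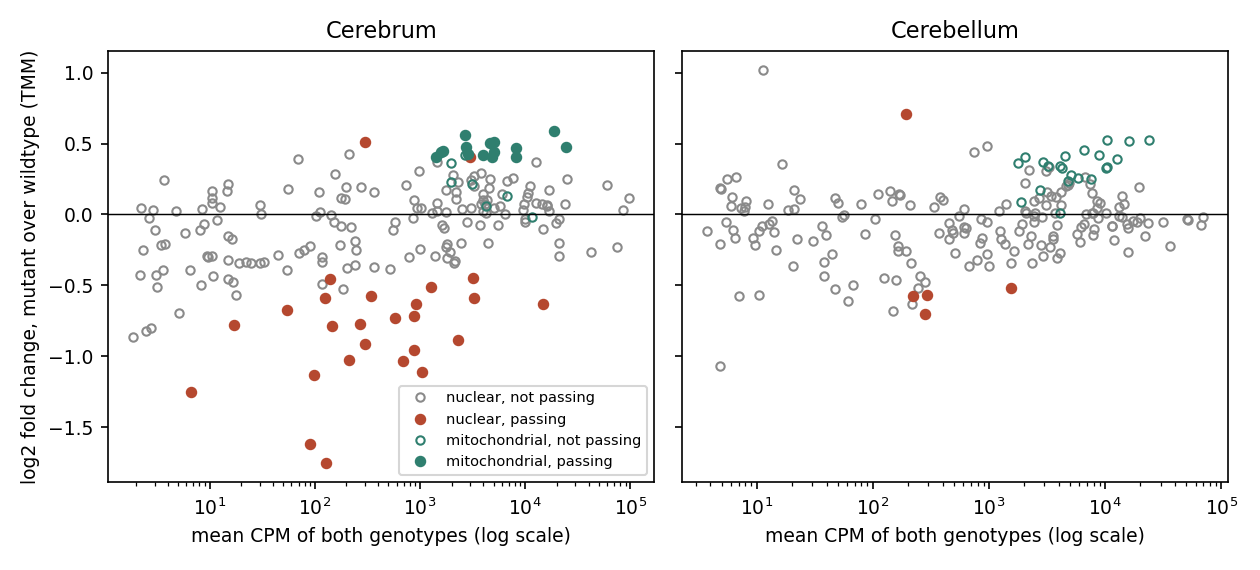
Log2 fold change of mutant over wildtype, scaled by TMM, against mean CPM on a log axis for each tRNA in cerebrum (left) and cerebellum (right), filled where the adjusted p was under 0.05. In cerebrum 24 nuclear tRNAs lie lower and 15 of the mitochondrial ones higher; scaled to the mitochondrial total the latter lose their call.

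Among lists fixed before the data were examined, 15 of 22 mitochondrial tRNAs rose in cerebrum and none fell (17 rose adjusted over the list alone; camera adjusted p = 6.1e-11 with a preset correlation, and adjusted p = 0.0257 with an estimated correlation). Isodecoders whose anticodon begins with adenosine, which is read as inosine, held 8 falls among 33 members, with 0 rises (9 fell adjusted over the list alone; camera adjusted p = 0.0074, but adjusted p = 0.221 with an estimated correlation and adjusted p = 0.0967 with nuclear tRNAs alone as background). The falls were in Ala-AGC-1-1, Ala-AGC-5, Arg-ACG-2-1, Leu-AAG-3-1, Thr-AGT-5-1, Thr-AGT-6-1, Val-AAC-2 and Val-AAC-4-1. Families with introns held 4 falls among 16 members (Tyr-GTA-1, Tyr-GTA-5-1, Leu-CAA-4-1 and Arg-TCT-5-1; 4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.691). Long variable arm tRNAs held 4 falls among 31 (4 adjusted over the list alone; camera adjusted p = 0.889) and Arg-TCT 1 among 5 (1 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.936). The lowest-abundance tercile of nuclear tRNAs had a median of −0.26 and 5 falls among 62 (4 adjusted over the list alone; camera adjusted p = 0.0624). The highest tercile had a median of 0.06, 4 falls and 1 rise among 62 (4 and 0 adjusted over the list alone). Its camera adjusted p was 0.278, and 0.462 with an estimated correlation. With nuclear tRNAs alone as background and the preset correlation, camera adjusted p was 0.00208, upward.

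By amino acid, falls in cerebrum numbered 4 of 11 valine isodecoders, 3 of 6 elongator methionine, 3 of 16 leucine, 2 of 21 alanine, 2 of 19 arginine, 2 of 14 threonine and 2 of 5 tyrosine. Glutamine (9 members), glycine (9), lysine (12), phenylalanine (3), serine (14) and tryptophan (4) held 1 fall each, and the same falls passed adjusted over each list alone. Arginine held 1 rise, also adjusted over the list alone, and cysteine 1 of 14, which was 0 adjusted over the list alone. Asparagine, aspartate, glutamate, histidine, isoleucine, initiator methionine and proline lists held 0 calls among 3 to 5 members. No amino acid list passed (camera), the lowest being valine (adjusted p = 0.095) and methionine (adjusted p = 0.278) and the highest asparagine (adjusted p = 0.889). For cysteine, glycine and leucine the median lay above 0 and the mean below it while camera pointed up, and for proline the median lay above 0 while the mean and camera pointed down. The number of lists passing was 4 without cerebrum mutant 3 or without wildtype 1, against 2 with all libraries.

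Summed by anticodon in cerebrum, 8 of 72 passed, 6 higher and 2 lower. Val-AAC fell from 960 ± 120 CPM (SD, n = 6) to 578 ± 87.9 CPM (SD, n = 4), a log2 fold change of −0.73 ± 0.15 (SE, edgeR adjusted p = 0.00126). Tyr-GTA fell from 20800 ± 3087 to 13250 ± 2846 CPM (−0.65 ± 0.14 SE, edgeR adjusted p = 0.00126). The 6 higher ones were mitochondrial: Val-TAC (0.51), Ser2-GCT (0.43), Leu2-TAG (0.42), Trp-TCA (0.39), Lys-TTT (0.39) and Met-CAT (0.36). Met-CAT-4-1 and Ala-AGC-1-1 had mean counts of 717.6 and 502.8 per library, against 107300 and 134800 for the Met-CAT and Ala-AGC totals. Those totals did not pass with TMM (−0.07 and −0.13, edgeR adjusted p = 0.898 and 0.619). Nor did the totals of Lys-TTT (−0.07), Val-CAC (0.01) and Ser-GCT (−0.04), which also held falling isodecoders. Scaled to the mitochondrial total, 0 anticodons were higher and 26 lower. Val-AAC, Tyr-GTA, Met-CAT, Ala-AGC, Lys-TTT and Ser-GCT were among these, and Val-CAC was not. The count of 8 with TMM moved with single libraries. It was 20 without cerebrum mutant 1, 3 without mutant 2, 5 without mutant 3, and 4 without wildtype 2 or wildtype 4. Val-AAC, Tyr-GTA and mitochondrial Val-TAC passed with any library left out. Of the other mitochondrial anticodons, Ser2-GCT did not pass without mutant 2, Leu2-TAG without mutant 2 or 3 or wildtype 2 or 4, Lys-TTT without mutant 2, 3 or 4 or wildtype 2 or 4, Trp-TCA without mutant 1 or 2 or wildtype 1, 2, 3, 4 or 5, and Met-CAT without mutant 2, 3 or 4 or wildtype 1, 2, 3, 4 or 5.

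In cerebellum, 5 of 202 tRNAs passed the edgeR test, 1 higher and 4 lower, and 40 had an unadjusted p under 0.05. Gly-CCC-2, a glycine tRNA, fell from 351 ± 32.7 CPM (SD, n = 6) to 216 ± 29.2 CPM (SD, n = 5), a log2 fold change of −0.70 ± 0.13 (SE, edgeR adjusted p = 0.00901). Gly-GCC-1 fell from 1835 ± 165 to 1282 ± 130 CPM (−0.52 ± 0.11 SE, edgeR adjusted p = 0.0149), Gly-CCC-3-1 by 0.57 and the serine tRNA Ser-AGA-2 by 0.58 on the log2 scale. Ser-CGA-3-1 rose from 146 ± 24.7 to 239 ± 26.4 CPM (0.71 ± 0.14 SE, edgeR adjusted p = 0.0145). Next by p, and not passing, were Arg-CCT-1-1 (−0.34), mitochondrial Phe-GAA (0.52; mt-Tf, mm10 chromosome M, 1 to 68, plus strand), Arg-TCT-4-1 (0.44), Gln-CTG-3 (−0.68) and Ala-AGC-1-1 (−0.63 ± 0.18 SE, edgeR adjusted p = 0.0519). The initiators iMet-CAT-1 (−0.27), iMet-CAT-2-1 (−0.15) and iMet-CAT-3-1 (−0.14), SeC-TCA-1-1 (−0.26), Arg-TCT-1-1 (−0.31), Arg-TCT-3-1 (−0.21), Ile-TAT-2 (0.15) and Ile-TAT-1-1 (0.01) did not pass either. On the mitochondrial scale iMet-CAT-1 (−0.64), SeC-TCA-1-1 (−0.64), Arg-TCT-1-1 (−0.68), Arg-TCT-3-1 (−0.59), Arg-CCT-1-1 (−0.69), Gln-CTG-3 (−1.08) and Ala-AGC-1-1 (−0.94) passed, and the other initiators (both −0.53) did not. On that scale Ile-TAT-2 and Ile-TAT-1-1 lay at −0.15 and −0.29 and did not pass, and Ser-CGA-3-1 stayed above 0 at 0.37 but did not pass; with the spike-in as the scale Phe-GAA and Arg-TCT-4-1 lay below 0.

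Mitochondrial tRNAs in cerebellum had a median of 0.34, and 0 of 22 passed alone (7 rose adjusted over the list alone; camera adjusted p = 8.57e-11, but adjusted p = 0.624 with an estimated correlation). Glycine isodecoders held 3 falls among 9 (3 adjusted over the list alone; camera adjusted p = 0.0437, but adjusted p = 0.624 with an estimated correlation). Glutamine isodecoders had a median of −0.35 and no member that passed over all tRNAs (1 fell adjusted over the list alone; camera adjusted p = 0.0437, but adjusted p = 0.839 with an estimated correlation). Arginine had 0 calls among 19 (1 rose and 3 fell adjusted over the list alone), serine 1 rise and 1 fall among 14 (the same adjusted over the list alone), and threonine 0 among 14 (2 rose and 1 fell adjusted over the list alone). The other amino acid lists except glycine and glutamine had 0 calls either way. Camera adjusted p for the amino acid lists that did not pass ran from 0.191 (arginine) to 0.999 (phenylalanine). Anticodons starting with adenosine held 1 fall among 33 (2 adjusted over the list alone; camera adjusted p = 0.403), families with introns 0 among 16 (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.629), long variable arm tRNAs 1 rise and 1 fall among 32 (the same adjusted over the list alone; camera adjusted p = 0.993) and Arg-TCT 0 among 5 (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.629). The lowest and highest abundance terciles held 0 calls among 60 each (0 adjusted over the list alone). Camera adjusted p was 0.285 and 0.629, and 0.839 for both with an estimated correlation. With nuclear tRNAs alone as background and the preset correlation, the highest tercile had camera adjusted p = 0.0443, upward. For phenylalanine and the highest tercile median and mean lay below 0 while camera pointed up, and for threonine only the mean lay below 0. The number of lists passing was 1 without cerebellum mutant 3 or without wildtype 2, against 3 with all libraries. The glycine list did not pass without mutant 3 or 5 or wildtype 2, nor the glutamine list without mutant 2, 3 or 4 or wildtype 1 or 2.

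The cerebellum count of tRNAs depended on scale and on single libraries. Scaled to the mitochondrial total, the median of all tRNAs moved from −0.03 to −0.37 and that of nuclear ones from −0.06 to −0.40, and 53 tRNAs passed, 0 higher and 53 lower. With TMM, 33 passed without cerebellum mutant 5, 12 without mutant 3, 3 without mutant 1, mutant 2, wildtype 4 or wildtype 5, and 2 without wildtype 1 or wildtype 6. Gly-CCC-2 and Ser-CGA-3-1 passed with any library left out; Gly-GCC-1 did not without wildtype 1 or 6. Gly-CCC-3-1 and Ser-AGA-2 did not pass without mutant 1, 2 or 4 or wildtype 1, 4, 5 or 6, nor Ser-AGA-2 without wildtype 3, and their edgeR adjusted p reached 0.115 and 0.109. With depth class as a covariate 0 passed by edgeR (38 at unadjusted p under 0.05): Gly-CCC-2 stood at −0.64 ± 0.16 (SE, edgeR adjusted p = 0.0682) and Ser-CGA-3-1 at 0.76 ± 0.19 (SE, edgeR adjusted p = 0.0682), with larger errors than without it. With that covariate and mitochondrial scaling 48 passed, all lower, but 0 by edgeR without cerebellum mutant 1 (18 at unadjusted p under 0.05), and 70, all lower, without wildtype 5.

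None of 71 anticodons passed in cerebellum by edgeR (17 at unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom). The lowest p-values were those of Ser-AGA (log2 fold change −0.54 ± 0.15 SE, edgeR adjusted p = 0.0853) and of mitochondrial Phe-GAA (0.46), Tyr-GTA (0.46) and Trp-TCA (0.45). With the spike-in as the scale these 3 mitochondrial values lay below 0. Scaled to the mitochondrial total 11 passed, all lower; with TMM the count was 11 without cerebellum mutant 5, 5 without mutant 3 and 1 without wildtype 2.

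The direct test of the tissues against each other found 10 of 204 tRNAs whose genotype effect differed (edgeR), and in each the fold change was higher in cerebellum. The largest differences were in Met-CAT-4-1 (1.28 ± 0.32 SE, edgeR adjusted p = 0.0133), Leu-CAA-4-1 (1.18 ± 0.28), Val-CAC-1-1 (1.01 ± 0.23), Ala-AGC-1-1 (0.97 ± 0.25), Ser-GCT-1-1 (0.96 ± 0.25) and Thr-AGT-6-1 (0.91 ± 0.20). All 6 had fallen in cerebrum. In cerebellum Met-CAT-4-1 measured 328 ± 70.9 CPM (SD, n = 6) in wildtype and 236 ± 89.8 CPM (SD, n = 5) in mutants, which did not pass. Scaled to the spike-in, 0 tRNAs differed between the tissues by edgeR (14 at unadjusted p under 0.05), and with TMM DESeq2 gave 17, 16 higher and 1 lower. Without cerebellum mutant 5 the count was 21, 15 higher and 6 lower. With a block on genotype and replicate number it was 28, 17 higher and 11 lower. Ser-GCT-1-1 did not pass without cerebrum mutant 3 or 4, nor Ala-AGC-1-1 on the mitochondrial scale. Depth class, nearly the same split as genotype in cerebellum, was not fitted for this difference.

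**Figure D3:**
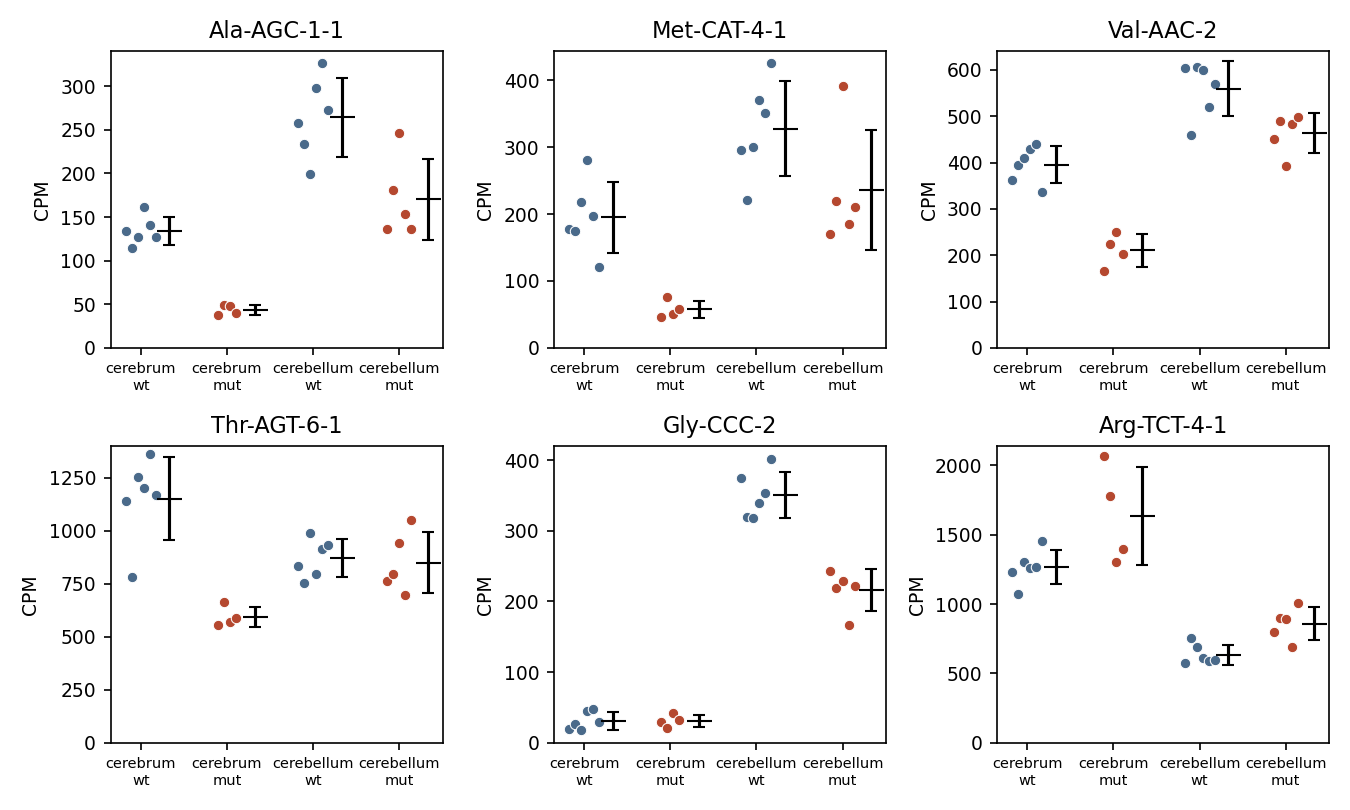
CPM of 6 named tRNAs in each library (points) with the group mean and SD beside them, TMM scaled within each tissue. Ala-AGC-1-1 lies between 37.8 and 49.7 in cerebrum mutants, below the wildtype range of 114.9 to 161.8.

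**Figure D4:**
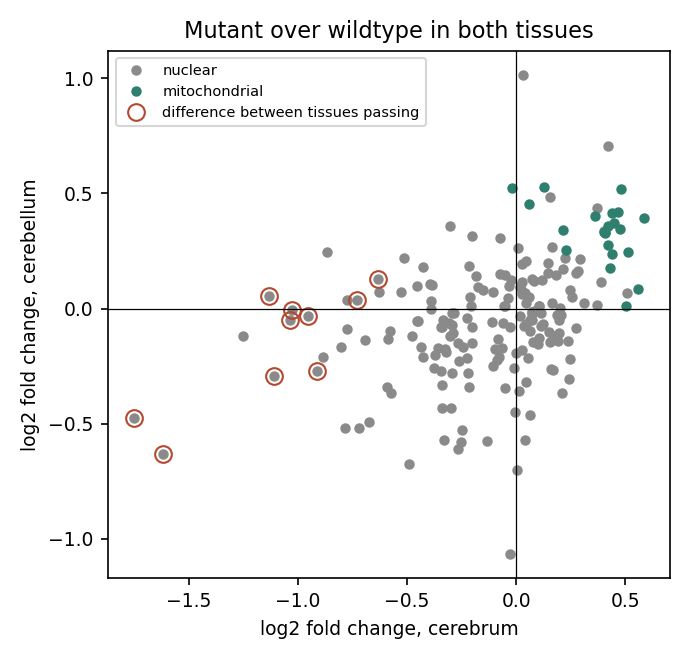
Log2 fold change of mutant over wildtype in cerebrum (horizontal) and cerebellum (vertical) for each tRNA, with rings on the 10 whose difference between the tissues passed. Of the 24 nuclear tRNAs that fell in cerebrum, 17 lie below 0 in cerebellum, where 112 of all 180 nuclear tRNAs (62.2%) lie below 0.

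In wildtype mice the tRNA pools of the tissues were far apart: 145 of 204 tRNAs passed (edgeR), 68 higher and 77 lower in cerebellum. Histidine tRNAs were higher, with His-GTG-1-1 at 3.50 ± 0.27 (SE), His-GTG-3-1 at 2.20 ± 0.25 and His-GTG-2 at 1.78 ± 0.15 on the log2 scale. Gly-CCC-2 rose from 34.2 ± 14.98 CPM (SD, n = 6) in cerebrum to 312.5 ± 32.4 CPM (SD, n = 6) in cerebellum (3.20 ± 0.22 SE, edgeR adjusted p = 1.34e-12), followed by Glu-TTC-3 (2.36) and Val-AAC-5-1 (2.83-fold). The lowest were Sup-TCA-1-1 (−2.12), Gln-TTG-5-1 (−2.07), Cys-GCA-10-1 (−1.87), Pro-TGG-3-1 (−1.82), iMet-CAT-2-1 (−1.60) and Ser-AGA-1-1 (−1.41). Mean counts per library were only 27.5 for Sup-TCA-1-1, 32.4 for Gln-TTG-5-1, 49.6 for Cys-GCA-10-1, 57.4 for Ser-AGA-1-1 and 56.4 for His-GTG-3-1. Each tissue has its own count table, so a difference between library batches cannot be told apart from tissue. The named tRNAs kept their direction on each scale tried, but the split was 85 higher and 55 lower with library totals, and 6 higher and 138 lower with the spike-in as the scale, where the median of all tRNAs moved from −0.05 to −0.99.

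The authors' deposited tables of DESeq2 results list 121 cerebrum tRNAs at an adjusted p under 0.05, 120 lower and 1 higher in mutants, and 51 cerebellum tRNAs, all lower. In the authors' deposited table for cerebrum tRNAs the printed fold change runs from mutant to wildtype, with r = −1 against mutant over wildtype from the counts, and its sign was turned here. The other deposited tables run the opposite way. Mean levels in the authors' deposited tRNA tables matched counts scaled by the mitochondrial tRNAs to within 0.450% in cerebrum and 0.186% in cerebellum. Of the cerebrum tRNAs passing in the authors' deposited table, 105 passed here in the same direction with mitochondrial total scaling and 25 with TMM; for cerebellum these numbers were 48 and 4.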

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

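Tests on the spike-in, on the few abundant tRNAs, on depth class and on leaving out cerebellum mutant 5 were chosen after the results were seen; thinning, the isodecoder tests and the splits, other than those within depth classes, were not.

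In 14 of 114 groups of values, 1 library stood far from the others of its group. Chance gives about 1 in 20 groups if values are normal and groups independent. These groups share libraries and are not independent, so 14 cannot be read as an excess over chance. In cerebellum mutant 5, iMet-CAT-1 was at 21900 CPM, iMet-CAT-3-1 at 279 CPM and SeC-TCA-1-1 at 2140 CPM, all above the other mutants. Cerebrum mutant 1 had Arg-TCT-1-1 at 4290 CPM, above the others, and Ile-TAT-1-1 at 1970 CPM, below them. Val-CAC-1-1 was at 169 CPM in cerebrum mutant 2 (others 130 to 132) and at 181 CPM in cerebrum wildtype 6 (others 290 to 319). Cerebrum wildtype 2 was low for Cys-GCA-MT at 861 CPM and for Thr-AGT-6-1 at 782 CPM, and wildtype 4 for Arg-TCT-3-1 at 1310 CPM. The mitochondrial share of cerebrum wildtype 1 was 10.4%, below the others. In cerebellum, Gly-CCC-2 was at 167 CPM in mutant 4 and Arg-TCT-1-1 at 5880 CPM in wildtype 3, and wildtype 5 had a total of 5360000 counts, above the other wildtype libraries.

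The genotype effect differed between the tissues, by a test of the difference itself, for Met-CAT-4-1 (1.28), Leu-CAA-4-1 (1.18), Val-CAC-1-1 (1.01), Ala-AGC-1-1 (0.97), Ser-GCT-1-1 (0.96) and Thr-AGT-6-1 (0.91), log2 fold change in cerebellum minus cerebrum. The count of 10 such tRNAs was reached by 1 of 100 splits, the real one, and the highest other split gave 9. Chance is thus unlikely at that level, though by a narrow margin. These splits do not address depth class, nearly the same split as genotype in cerebellum, which was not fitted for this difference.

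For the higher mitochondrial share in mutants the design offers a candidate explanation, a smaller nuclear tRNA pool when RNA polymerase III is impaired. A rise of mitochondrial tRNA with no fall of nuclear tRNA is argued against by log2 nuclear counts per spike-in count, −0.36 in cerebrum and −0.57 in cerebellum, each over 2 standard errors below 0 though not past adjustment, and the test assumes an equal spike per amount of RNA. A fall of a few abundant tRNAs is argued against, since 97.8% of nuclear tRNAs in cerebrum and 97.2% in cerebellum lay below 0 on the mitochondrial scale. In cerebellum, depth class is nearly the same split as genotype: the within-class difference was 5.10 percentage points, in classes too small for its test to reach p under 0.05, and of 30 splits within depth classes 1, the real one, gave 48 tRNAs on the mitochondrial scale with depth class as a covariate (highest other 0), but 0 passed by edgeR without cerebellum mutant 1 (18 at unadjusted p under 0.05) and 70 without wildtype 5, each alone of its genotype in its class. Another of the 30 splits came near the real one in its median nuclear change, −0.52 against −0.55. It had 62 tRNAs at unadjusted edgeR p under 0.05, against 92 in the real split. A smaller nuclear pool thus may hold in cerebrum as a hypothesis, and a shift between depth classes stays open beside it in cerebellum, where the evidence against it rests on 1 library.

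In cerebrum mutants, minor isodecoders were lower relative to the most abundant isodecoder of the same anticodon. Low counts alone are argued against, since the difference was −0.18 ± 0.03 (SE) with isodecoders of mean count at least 1000 (exact permutation p = 0.00952). Reads shared with the major isodecoder to the same extent in both genotypes carry its change into the minor one and so shrink a difference. The difference of −0.24 ± 0.04 (SE) is the pattern itself and no separate test, so only this reasoning speaks against such sharing as the cause. Sharing or misassignment of reads that differs between genotypes, for instance through altered modification, could not be tested; a shift of the isodecoders themselves stays open beside it as a hypothesis.

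Fewer tRNAs passed in cerebellum (5) than in cerebrum (41). Lower depth is argued against: thinning the cerebrum counts to the median shallow total gave a median of 44 calls (40 to 47 over 20 draws). A single library is a candidate explanation, since 33 tRNAs passed without cerebellum mutant 5. Depth class stays open: its covariate, nearly the same split as genotype, left 0 calls, with Gly-CCC-2 going from −0.70 ± 0.13 to −0.64 ± 0.16 (SE), so the calls ended largely through larger errors. The interaction test above found a difference between the tissues for 10 tRNAs with TMM, 0 with the spike-in as the scale and 28 with the replicate block. In the simulated sets it recovered 35.2% of 1.5-fold and 83% of 2-fold differences, so the tRNAs that did not pass stay open.

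The libraries were split 100 times into groups of the same sizes, the real split included. Only the real split gave as many tRNAs as the cerebrum comparison (41, highest other 14), the cerebellum comparison (5, highest other 3) and the wildtype tissue comparison (145, highest other 109). Chance is thus unlikely for these counts at a level of 1 in 100, though by a narrow margin in cerebellum. There the splits do not address depth class, nearly the same split as genotype. For cerebrum anticodons 3 splits, the real one included, gave 8 or more, a share under the bound set beforehand. Another split gave 11, more than the real one, so chance is not firmly excluded. Cerebellum anticodons had 0 calls, which all 100 splits reach (highest other 4). For the number of lists chance cannot be excluded: 80 splits gave at least the 2 cerebrum lists (highest other 13) and 78 at least the 3 cerebellum lists (highest other 12), several times the real counts, which points to tRNAs that vary together across libraries. For single lists, taken up because they passed and so no independent check, a p as low as the real one came from 1 of 100 splits for the mitochondrial list and 4 for anticodons starting with adenosine in cerebrum, and from 9, 20 and 7 for the mitochondrial, glutamine and glycine lists in cerebellum. Parting the libraries by sex gave 0 calls in either tissue and parting cerebellum by depth class gave 0.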

How the results depend on the processing

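Spike-in scaling, the median of ratios over mitochondrial tRNAs, depth class as a covariate, differences within depth classes leaving out cerebellum mutants 1 and 5, and leaving out mutant 1 under the covariate were chosen after seeing the data. The 12 named cerebrum falls kept their sign in all settings in which they were tested, and Met-CAT-6-1 alone lost its call in any. Counts depended on the scale; the cause was not tested except where the construction shows it. Scaled to the mitochondrial total, counts were 111 (cerebrum tRNAs), 53 (cerebellum tRNAs), 26 (cerebrum anticodons) and 11 (cerebellum anticodons). With the mitochondrial median of ratios they were 117, 30, 33 and 10, and 5 for the difference between tissues. With spike-in scaling they were 74, 83, 5 and 16, and 0 for the difference between tissues. These scales hold mitochondrial tRNA or the spike-in constant, so a shift of the nuclear pool enters each fold change.

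The main cerebellum count of 5 was 9 with library totals, 23 with DESeq2, 9 with limma-voom, 9 with no filter, 8 with a mean count of at least 50, 3 with sex as a covariate, 16 in the joint fit, 0 with depth class as a covariate, 48 with that covariate and mitochondrial scaling (0 by edgeR without cerebellum mutant 1, 18 at unadjusted p under 0.05), and 24 without cerebellum mutants 1 and 5. For cerebellum anticodons DESeq2 gave 3, and depth class with mitochondrial scaling gave 7. The cerebrum anticodon count was 4 with a mean count of at least 50 and 2 with nuclear tRNAs only. The difference between tissues gave 17 with DESeq2. With an estimated correlation 1 list passed in cerebrum and 0 in cerebellum, and with fry 5 and 1. With nuclear tRNAs as background 1 list passed in cerebrum, the highest-abundance tercile (adjusted p = 0.00208, upward), and the list of anticodons starting with adenosine did not (adjusted p = 0.0967); in cerebellum that tercile (0.0443, upward), glutamine and glycine passed.

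The labels do not say that equal numbers mark the same animal, and the libraries were not taken as paired, though sex matched in all 10 pairs of one genotype and number across tissues, so a shared animal stays open. Correlations of deviations ran from −0.156 to 0.460 across tissues, from −0.289 to 0.557 within cerebrum and from 0.022 to 0.215 within cerebellum; 6 of 10, 3 of 4 and 1 of 5 were over 0.1, and 2 of 10, 1 of 4 and 0 of 5 correlated best with their own number. With the replicate block the counts were 65 (cerebrum tRNAs), 5 (cerebellum tRNAs), 27 (cerebrum anticodons), 0 (cerebellum anticodons), 28 (difference between tissues, 17 higher and 11 lower in cerebellum, the 10 without the block among them) and 155 (wildtype tissues), with 3 and 2 lists. Within a tissue the block joined mutant and wildtype libraries of equal number, which cannot share an animal. Sex matched in 1 of 4 such pairs in cerebrum and 2 of 5 in cerebellum. Paired the same way, the mitochondrial share differed by 3.25 points in cerebrum and 3.55 in cerebellum. Exact permutation p was 0.125 and 0.0625, the smallest these tests allow.

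The mitochondrial share difference was 3.07 points in male and 3.13 in female cerebrum libraries, and 4.33 and 3.11 in cerebellum. These subsets are too small for their exact permutation tests to reach p under 0.05, whatever the values. Within depth classes the difference was 5.10.

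Leaving out each library in turn gave 34 to 51 for cerebrum tRNAs, 2 to 33 for cerebellum tRNAs, 3 to 20 for cerebrum anticodons, 0 to 11 for cerebellum anticodons, 7 to 21 for the difference between tissues, 137 to 152 for wildtype tissues, 2 to 4 lists in cerebrum and 1 to 4 in cerebellum. The share difference ran from 2.67 to 3.61 points in cerebrum and from 2.74 to 4.54 in cerebellum, passing each time. Depth was lowest in 6 cerebellum libraries, at most 2286338 counts; cerebrum counts thinned to the median of these totals gave a median of 44 calls (40 to 47 over 20 draws), so this depth did not lower the cerebrum count.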

Other observations

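The tests of both tissues across tRNAs were chosen after the result was seen; the isodecoder tests were set before theirs.

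Over 42 anticodons with at least 2 measured isodecoders in cerebrum, the minor ones lay lower in mutants relative to the major one in 34, or in 23 of 34 with a mean count of at least 1000. The mean difference between genotypes was −0.24 ± 0.04 (SE) on the log2 scale (exact permutation p = 0.00952, the smallest that 210 splits allow; adjusted p = 0.0286 over 6 tests). In cerebellum the minor ones lay lower in 32 of 42, or in 24 of 34 with that mean count, and the mean difference was −0.08 ± 0.05 (SE, exact permutation p = 0.117). A p of 0.05 or more had been set beforehand as evidence against a change, which was wrong, since it sets no bound on a difference 0.05 in error, so the cerebellum stays open; whether the tissues differ in it was not tested.

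tRNAs named for a single locus were lower in cerebrum mutants relative to those merged over several copies, by −0.12 ± 0.04 (SE; exact permutation p = 0.019, adjusted p = 0.038). In cerebellum the difference was 0.07 ± 0.04 (SE; exact permutation p = 0.117). Single-locus tRNAs were also less abundant. In wildtype their mean log2 CPM relative to merged ones was −3.17 in cerebrum and −3.05 in cerebellum. No test at matched abundance was run, so the cerebrum difference cannot be told apart from one by abundance. Gene copy number itself was not measured, and the cerebellum value has the opposite sign but, for the reason given above, decides nothing.

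Differences of mean log2 CPM, mutant minus wildtype, had a Pearson r of 0.313 between the tissues across nuclear tRNAs, which are not independent replicates; for the log2 fold changes fitted by edgeR it was 0.288 over 178 tRNAs. Other splits of the cerebrum libraries reached 0.482 (exact permutation p = 0.2), so a change shared by both tissues was not shown by this measure.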
